A study of Mus musculus with 9 samples.

How the data were processed

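RNA was measured in 9 libraries of Mac1+ bone marrow cells of C57BL/6 mice, each from 100 cells sorted directly into lysis buffer and prepared with Smart-seq2, a full-length method that does not mark strand, per the labels' protocols. The deposited values are RPKM per gene symbol in 1 table of 23420 symbols with a column for each library, made by the authors. STAR 2.4.2a, SAMtools 1.1 and HTSeq 0.6.1p1 and the build mm10 are named per the submitters' processing notes, with no role or order. The annotation, the counting settings, the treatment of duplicates and the scaling of RPKM are not given in the sources used here. Without strand, reads of overlapping or antisense genes cannot be told apart, and near-identical copies may share reads.

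Depth was read from the deposited RPKM. Of 15566 genes above 0 in any library, 15564 gave whole reads for a length between 20 and 30000 bp with a tolerance of 0.0001 reads (99.98% of values above 0). The smallest fitting length was taken, so reads of some genes may be undercounted. Recovered reads were 8836389, 2825728, 7510673 and 13301867 in DKOITD libraries 1 to 4, 5108022 and 13744891 in ITD libraries 1 and 2, and 23124435, 16085911 and 14770406 in WT libraries 1 to 3. The denominator, fixed by 229 genes whose GENCODE vM21 exon lengths fit it, in each RPKM column was 1.37, 1.29, 1.44 and 1.13 times these reads in DKOITD, 0.919 and 0.853 times in ITD, and 0.810, 0.703 and 0.784 times in WT, with a geometric mean of 1.00. The columns therefore differ from RPKM scaled to their own recovered reads by a factor per library. Lengths were fitted from the values, so the reads serve only for depth and 2 alternatives. PCR reads without molecular identifiers are not independent molecules.

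Groups and replicate numbers were taken from the sample titles. No pair of libraries held identical values, and the highest correlation of a pair across genes was 0.931. Genes with RPKM of at least 1 in at least 2 libraries were kept (10868), and log2(RPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), all 9 libraries in one fit with genotype group as the only factor. Each of the 3 comparisons was tested two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates changes of low genes, and where a group is listed at 0 the difference depends on the pseudocount. In this text, log2 differences without a printed p passed that threshold wherever a gene is said to rise or fall.

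There were 19 gene lists: T lineage, B lineage, early lymphoid and early thymic progenitor, haematopoietic stem and progenitor, HOX genes and cofactors, developmental regulators repressed by PRC2, PRC2 and RUNX complex components, neutrophil primary granule, neutrophil secondary granule, monocyte and macrophage, dendritic cell and MHC class II, eosinophil with basophil and mast cell, NK and cytotoxic, erythroid and megakaryocyte, proliferation, interferon response, FLT3 with STAT5 and MAPK response, immediate early and stress, and mitochondrial transcripts. Lists with at least 5 tested members (17) were tested with limma camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation, where no list passed in any comparison. The lists, the tests and the main alternatives were fixed before the data were examined.

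Genes named in the text follow a rule fixed at the same time. Ezh2, Runx1, Flt3 and Itgam are named in every library. In each comparison the 10 largest rises and the 10 largest falls past the threshold are named where the groups do not overlap, leaving out predicted or unnamed models, ribosomal protein copies and small RNAs. Up to 3 members of each list past the threshold are added by size of change, and where fewer than 5 genes pass, the 5 with the smallest p are named as not past it. Other genes are named with the statement that they were chosen after their values were seen, which also holds for Batf3 and Trf in the fit with the label number series. Gene positions are from GENCODE vM21, in the coordinates of mm10, matched by symbol.

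The gene test was tried on simulated data of the same size, with 200 changed genes in each of 20 runs over 10868 genes. For DKOITD against WT it called 91.6% of 8-fold, 43.8% of 4-fold and 3.43% of 2-fold changes in the right direction, and 6.14% of its calls were false. For DKOITD against ITD the shares were 79.8%, 30.7% and 1.49%, and for ITD against WT 66.5%, 23.6% and 0.522%. A list of 25 genes shifted 2-fold passed in 20 of 20 runs of each comparison, and an unchanged one in 1, 0 and 0. The simulated genes varied independently, whereas the estimated correlation was 0.57 within the dendritic list and 0.72 within the interferon list. These runs therefore do not give the rate of false list calls in the real data. Complexity measures were compared with exact permutation tests.

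Alternatives were another pseudocount, no filter and a stricter one, quantile and median-of-ratios scaling, no variance trend, library weights, a fit of the compared groups alone, a replicate block, an estimated inter-gene correlation and leaving out each library. Chosen after seeing the data were scaling per recovered read, limma voom on recovered reads, the label number series as a term, and leaving out WT 2 together with DKOITD 2 or with DKOITD 4. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.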

Results

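Gene expression was measured by RNA sequencing in 9 libraries of Mac1+ bone marrow cells from C57BL/6 mice, each made from 100 sorted cells. Mac1 is the integrin αM chain, a surface marker of granulocytes and monocytes, encoded by Itgam. The libraries fall into 3 genotype groups. The DKOITD group (n = 4) carried floxed Ezh2 and Runx1 alleles, a Rag1Cre transgene and 1 Flt3 internal tandem duplication (ITD) allele. The ITD group (n = 2) carried the Flt3 ITD allele without Cre, and the WT group (n = 3) carried floxed alleles with neither Cre nor ITD. Ezh2 is the methyltransferase of the polycomb repressive complex PRC2, Runx1 a transcription factor of blood cells, and Flt3 a receptor kinase of early progenitors and dendritic cells. The series title ties these alleles to leukaemia of early thymic progenitors. The comparisons ask how Mac1+ marrow cells differ between the genotypes. The sources used here do not say whether any animal had leukaemia at harvest, and leukaemic cells in the gate are not ruled out. The labels do not say that each library came from its own animal, so the p-values measure only the spread between these libraries.

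Whole reads recovered from the deposited values came to between 2825728 (DKOITD 2) and 23124435 (WT 1) per library. DKOITD libraries held more genes above 0 than the 5 others, at 11519 ± 198 (SD, n = 4) against 10700 ± 356 (SD, n = 5; exact permutation test, two-sided, p = 0.0159). Their 100 highest genes took 56.5% ± 9.44 (SD, n = 4) of summed RPKM, against 82.2% ± 2.81 in the others (SD, n = 5; exact permutation test, two-sided, p = 0.00794, the smallest this design allows). S100a8 and S100a9, the abundant calcium-binding proteins of neutrophils, together held 5.75% ± 4.23 of reads in DKOITD (SD, n = 4). They held 27.7% ± 3.51 in WT (SD, n = 3; exact permutation test, two-sided, p = 0.0286, the smallest p for 4 against 3). WT 2 stood apart from the rest, with a median correlation across genes of 0.759 with the 8 other libraries, while the other libraries lay between 0.815 and 0.881. Genes are not independent replicates in such a correlation.

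**Figure D1:**
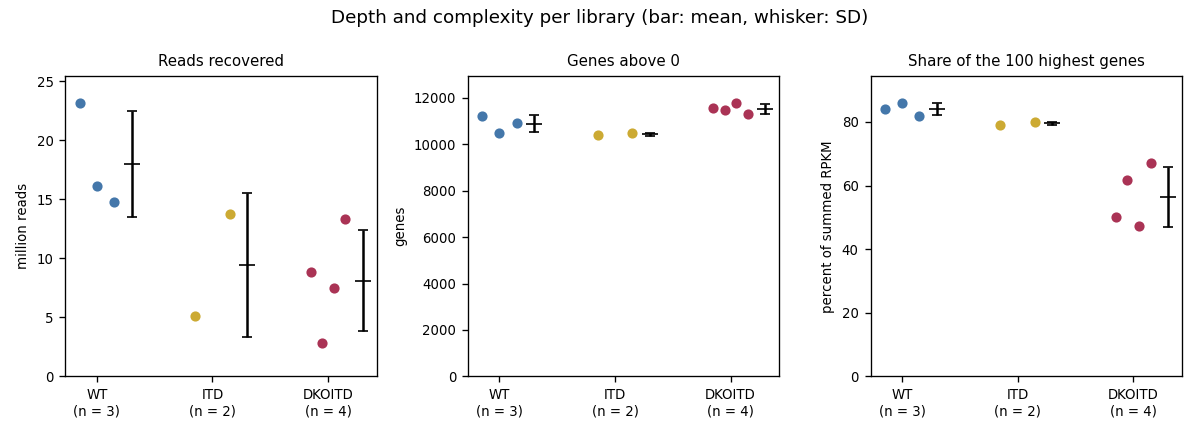
Reads recovered, genes above 0 and the share of summed RPKM in the 100 highest genes (percent) for each library (points), with group mean and SD (bar and whisker). The 4 DKOITD libraries lie between 47.2% and 67.1% in the share of the highest genes, and the 5 other libraries between 79.1% and 85.8%.

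The targeted genes were read first. Ezh2 (chromosome 6, 47530139 to 47595341 in mm10) measured 18.1, 1.54, 8.04 and 10.2 RPKM in DKOITD libraries 1 to 4. It measured 12.9 and 19.0 RPKM in the ITD libraries and 9.69, 2.05 and 12.4 RPKM in the WT libraries. Runx1 (chromosome 16, 92601466 to 92826149) measured 16.4, 14.9, 17.6 and 10.4 RPKM in DKOITD, 4.42 and 4.42 RPKM in ITD, and 10.7, 13.02 and 3.53 RPKM in WT. Neither gene passed the test in any comparison, with Ezh2 at a log2 difference of 0.14 ± 0.69 (SE; adjusted p = 0.913) and Runx1 at 0.78 ± 0.46 (SE; adjusted p = 0.269) between DKOITD and WT. A value per gene does not resolve the floxed exons, so these levels check little about the deletion. The share of Mac1+ cells that had ever made Cre is not given in the sources used here.

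Flt3 (chromosome 5, 147330741 to 147400489) measured 34.5, 26.1, 39.2 and 8.80 RPKM in DKOITD, 0 and 10.4 RPKM in ITD, and 0.0146, 0.145 and 0 RPKM in WT. It rose in DKOITD against WT by a log2 difference of 4.56 ± 0.76 (SE; adjusted p = 0.00474). The sort marker Itgam (chromosome 7, 128062640 to 128118491) measured 10.98, 33.3, 24.8 and 39.0 RPKM in DKOITD, 78.1 and 97.3 RPKM in ITD, and 100.5, 143 and 90.3 RPKM in WT. Itgam fell by 2.11 ± 0.40 on the log2 scale in DKOITD against WT (SE; adjusted p = 0.00813), so the transcript of the sort marker itself differed between the groups.

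**Figure D2:**
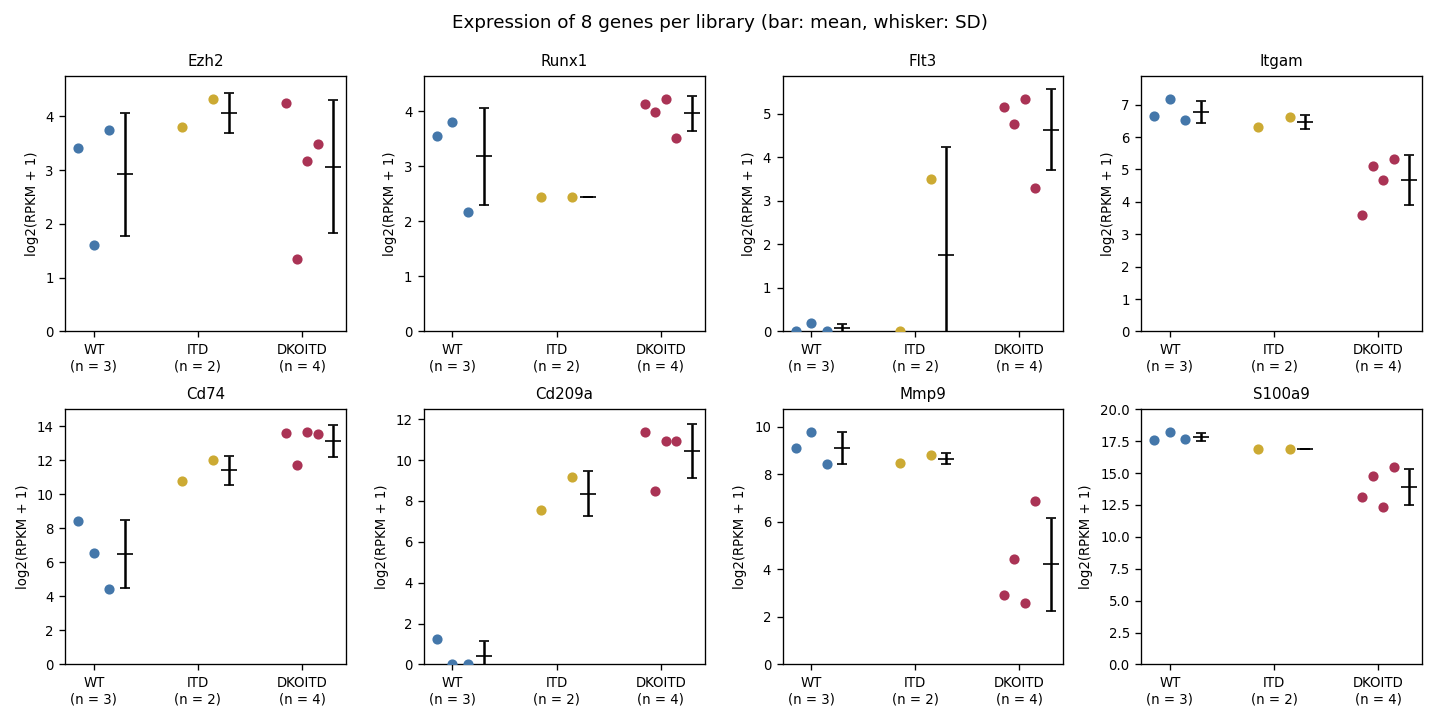
log2(RPKM + 1) of 8 genes in each library (points), with group mean and SD (bar and whisker, drawn from 0 upwards). Cd74 and Cd209a are higher in all 4 DKOITD libraries than in any WT library, Mmp9 and S100a9 are lower in all 4, and Ezh2 overlaps between the groups.

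DKOITD against WT asks what the combined alleles change in Mac1+ cells. Genes of antigen presentation by dendritic cells rose in DKOITD and genes of maturing neutrophils fell. Cd74, the invariant chain of MHC class II, averaged 10238 ± 4569 RPKM in DKOITD (SD, n = 4) and 155 ± 174 RPKM in WT (SD, n = 3). Cd209a, a lectin of dendritic cells, averaged 1731 ± 968 RPKM (SD, n = 4) against 0.468 ± 0.810 RPKM (SD, n = 3). The gelatinase Mmp9 averaged 37.0 ± 53.1 RPKM (SD, n = 4) against 587 ± 262 RPKM (SD, n = 3), and S100a9 averaged 21475 ± 18203 RPKM (SD, n = 4) against 234334 ± 57322 RPKM (SD, n = 3).

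Of the 25 tested genes of the dendritic cell and MHC class II list, 21 rose and 0 fell over all genes tested, and 23 rose when adjusted over the list alone. Their median log2 difference was 3.50 (limma camera, adjusted p = 2.63e-17; adjusted p = 0.364 with an estimated correlation). The class II chains H2-Eb1, H2-Aa and H2-Ab1 rose by log2 differences of 8.28 ± 1.39, 7.56 ± 1.03 and 6.82 ± 0.89 (SE; adjusted p = 0.00481, 0.00205 and 0.00163). Cd209a rose by 10.01 ± 0.64 (SE; adjusted p = 2.35e-05), the lectin Clec10a by 6.79 ± 0.47 (SE; adjusted p = 2.58e-05) and Cd74 by 6.66 ± 0.77 (SE; adjusted p = 0.000838). Other large rises were Tmem176a (7.19), Tspan3 (6.75), Bcl2a1a (5.98), of a family of survival genes, and Cd83 (5.97), a surface marker of mature dendritic cells. Class II genes and Bcl2a1a have close relatives, among which the authors' counting can divide reads, so each one's level is uncertain. Tspan3 was listed at 0 in all 3 WT libraries, so its difference depends on the pseudocount.

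Of the 41 tested genes of the neutrophil secondary granule and maturation list, 26 fell and 0 rose over all genes tested, and 29 fell when adjusted over the list alone. The median log2 difference was -2.41 (limma camera, adjusted p = 1.33e-14; adjusted p = 0.364 with an estimated correlation). The list's mean log2(RPKM + 1) was 6.29 and 5.88 in DKOITD 1 and 3, but 7.87 and 7.82 in DKOITD 2 and 4. It was 8.40 and 8.58 in the ITD libraries and between 8.85 and 8.92 in WT, so DKOITD 1 and 3 carried most of the fall. Mmp9 fell by 4.90 ± 0.80 (SE; adjusted p = 0.00443), AA467197 by 4.72 ± 0.86 (SE; adjusted p = 0.0068) and S100a9 by 3.90 ± 0.62 (SE; adjusted p = 0.0041). S100a9 lost its call under quantile normalization and without a filter on low values. Of the 21 genes of the primary granule and promyelocyte list, 8 fell and 1 rose, or 10 fell and 1 rose when adjusted over the list alone (median -0.21; limma camera, adjusted p = 0.0208; adjusted p = 0.613 with an estimated correlation). The hexokinase Hk3 fell by 2.84 ± 0.37 (SE; adjusted p = 0.00173), while Hdc, the enzyme that makes histamine, and Nkg7 fell by 2.74 and 2.96. Among the settings that ended the call of the primary list were the fit without WT 3 and quantile normalization, and scaled per recovered read its median was 0.55 where that of all genes was 0.74. Further large falls were Trp53inp2 (-4.24), Olfml2b (-4.06), Arap3 (-3.76), Ly6g5b (-3.72), Cd24a (-3.64) and Actn1 (-3.55).

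The interferon response list was higher in DKOITD, with 6 of 45 members past the threshold over all genes tested and 15 when adjusted over the list alone, all of them higher. Its median log2 difference was 1.37 (limma camera, adjusted p = 0.000593; adjusted p = 0.801 with an estimated correlation). Ifi44 rose by 4.70, Phf11b by 4.14 and Usp18 by 3.41, all genes induced by type I interferon, and Phf11b and Usp18 overlapped between the groups. DKOITD 2 differed from its group, with a mean log2(RPKM + 1) of 2.80 over the list, while DKOITD 1, 3 and 4 gave 5.78, 5.58 and 5.55. The WT libraries gave 3.69, 3.05 and 3.85.

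The monocyte and macrophage list moved both ways, with 14 of 42 members up, among them the mannose receptor Mrc1 (4.15), Ms4a6b (3.05) and the lysosomal marker Cd68 (2.99), and 1 down. Adjusted over the list alone, 16 were up and 7 down (limma camera, adjusted p = 0.342). In the list of early lymphoid and early thymic progenitor genes, 4 of 21 rose and 3 fell, or 6 and 5 when adjusted over the list alone, and the list did not pass (adjusted p = 0.976). Its largest rises were the chemokine receptor Ccr7 (5.44), Flt3 and Cd7 (4.54, with overlapping groups). The difference of Ccr7 was identical against ITD, where Ccr7 was listed at 0, so its size depends on the pseudocount. Of the 13 stem and progenitor genes, 3 rose and 1 fell, or 4 and 2 when adjusted over the list alone (adjusted p = 0.862), with Cd34 at 2.96, Cd48 at 2.86 and Prom1 at -2.66. In the B lineage list 3 of 9 rose and 1 fell, or 4 and 1 when adjusted over the list alone (adjusted p = 0.0914). The risers were Fcrla (2.50), Cd79b (2.43) and Spib (2.33), a transcription factor also of plasmacytoid dendritic cells. In the NK and cytotoxic list 3 of 10 rose and 1 fell, or 4 and 2 when adjusted over the list alone (adjusted p = 0.132), with the chemokine Ccl5 at 5.76 (overlapping groups) and the receptor Klrk1 at 3.83. In the T lineage list 1 of 7 rose (Tox, 1.79), and 2 rose and 2 fell when adjusted over the list alone (adjusted p = 0.945).

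The list of developmental regulators repressed by PRC2 had 6 tested genes of 51, of which 2 rose, or 4 when adjusted over the list alone (median 1.48; limma camera, adjusted p = 0.0216; adjusted p = 0.364 with an estimated correlation). Their mean log2(RPKM + 1) was 0.55, 0.70 and 0.97 in WT 1 to 3. Genes this low in WT can pass the filter through DKOITD libraries alone, which favours rises, so the list test says little. The cell cycle inhibitor Cdkn1a rose by 1.73 ± 0.46 (SE; adjusted p = 0.031) and Eya1, a developmental transcription factor, by 1.48 ± 0.43 (SE; adjusted p = 0.0441). Without WT 1 or WT 3 the call of this list ended, as it did without a filter on low values, under quantile normalization, scaled per recovered read and with the label number series as a term. Of the 24 genes of the PRC2 and RUNX complexes, 1 fell, Phf1 (-2.37), and 0 passed when adjusted over the list alone (adjusted p = 0.543). The HOX genes and cofactors had 4 tested members, too few for a list test.

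The proliferation list was lower, with 3 of 52 members down over all genes tested and 0 when adjusted over the list alone (median -0.27; limma camera, adjusted p = 0.0216; adjusted p = 0.801 with an estimated correlation). The mitotic genes Cenpf, Ube2c and Top2a fell by 1.42, 1.31 and 1.26. Among the settings that ended the list's call were the fits without DKOITD 2 or WT 3, quantile normalization, library weights, limma voom and scaling per recovered read, where its median turned to 0.43 beside 0.74 for all genes. The erythroid and megakaryocyte list was lower, with 1 of 13 past the threshold under both adjustments, Nfe2 (-1.83), a factor of both lineages (limma camera, adjusted p = 0.0102; adjusted p = 0.364 with an estimated correlation). That call ended without WT 1, and without both WT 2 and DKOITD 4. The globin Beta-s, with near-identical copies, was listed at 17103, 5372 and 17.0 RPKM in the WT libraries and at most 0.289 RPKM in DKOITD.

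In the FLT3, STAT5 and MAPK response list 3 of 29 rose and 4 fell, or 6 and 5 when adjusted over the list alone (adjusted p = 0.976). The risers were the cytokine signalling inhibitor Socs2 (3.28), Myc (3.02) and the cyclin Ccnd2 (2.99). In the immediate early and stress list 3 of 31 rose and 2 fell under both adjustments (adjusted p = 0.862), with Atf3 at 3.04, Cd69 at 2.79 (overlapping groups) and Gadd45a at -2.38. The list of eosinophil, basophil and mast cell genes had 1 of 6 lower under both adjustments, Hdc (adjusted p = 0.543). No symbol of the mitochondrial transcript list was found among the genes.

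**Figure D3:**
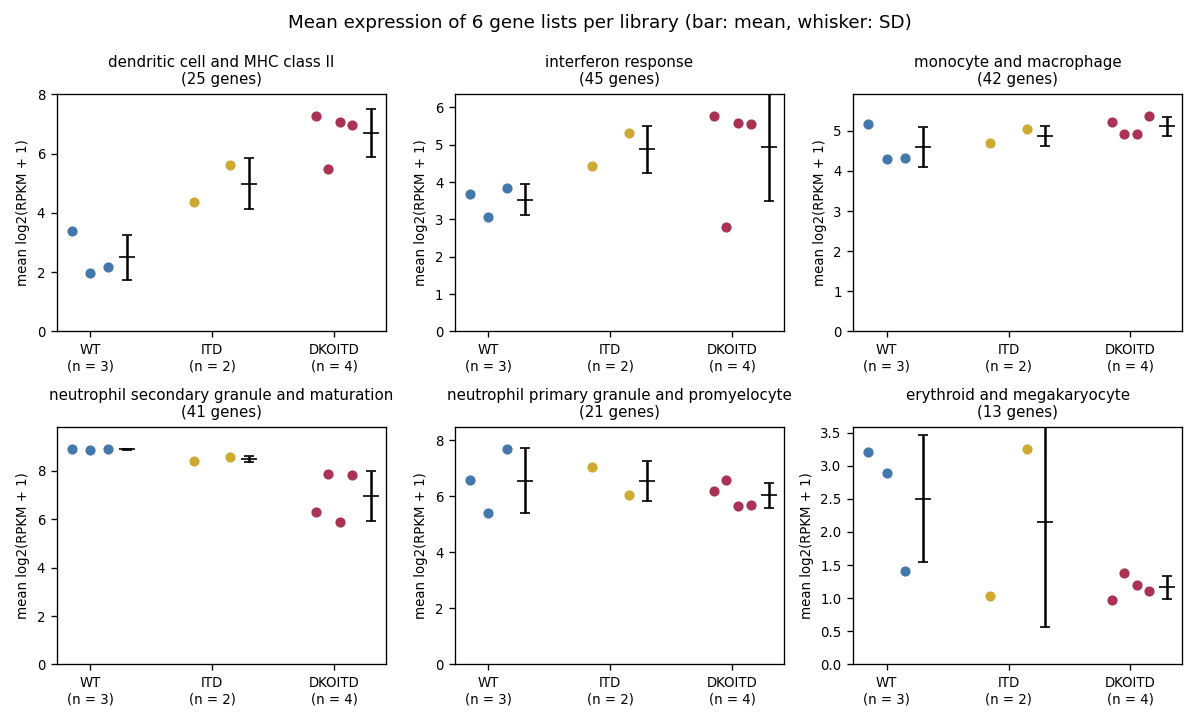
Mean log2(RPKM + 1) of 6 gene lists in each library (points), with group mean and SD (bar and whisker, drawn from 0 upwards). The dendritic list lies between 5.49 and 7.28 in DKOITD and between 1.97 and 3.38 in WT, and the interferon list lies at 2.80 in DKOITD 2.

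In total 1380 of 10868 genes changed between DKOITD and WT, 807 up and 573 down (limma, Benjamini-Hochberg adjusted p under 0.05), with a median log2 difference of all genes of 0.17. The groups did not overlap in 25.05% of all tested genes, where chance gives 5.71%. Among the named genes, Atf3, Beta-s, Ccl5, Cd68, Cd69, Cd7, Cdkn1a, Cenpf, Eya1, Nkg7, Phf1, Phf11b, Spib, Top2a, Tox, Ube2c and Usp18 lost their call with at least 1 library left out. The count was 611 without DKOITD 1, 541 without DKOITD 3, 766 without WT 2, 792 without both WT 2 and DKOITD 2, and 735 without both WT 2 and DKOITD 4. Under quantile normalization 678 genes rose and 767 fell, and scaled per recovered read 2525 rose and 247 fell. DKOITD libraries 1 to 3 carry label numbers from 228 to 274 and the 6 other libraries numbers from 385 to 393, and what the numbers mean is not stated. With that number series as a term only DKOITD 4 carries the comparison, and 4 genes passed (Cd209a, Clec10a, Batf3 and Trf, all higher). In that fit Cd74 stood at 7.08 ± 1.23 (SE; adjusted p = 0.0911), beside 6.66 ± 0.77 without the term, and Mmp9 at -2.23 ± 0.69 (SE; adjusted p = 0.346), beside -4.90 ± 0.80. The mean of the dendritic list differed there by 4.46 ± 1.01 and that of the secondary granule list by -1.07 ± 0.771 (SE, linear model over 9 libraries).

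DKOITD against ITD asks what differs with Rag1Cre where both groups carry floxed alleles and the Flt3 ITD allele, with the deletion itself not checked. DKOITD 1 to 3 also lie outside the label number series of both ITD libraries, so series and genotype cannot be told apart here either. Fewer genes passed, with 17 up and 6 down (23 of 10868; limma, adjusted p under 0.05), beside 1701 genes at an unadjusted p under 0.05 and a median log2 difference of all genes of 0.11. Chance gives 543 genes at that unadjusted p. The groups did not overlap in 31.3% of all tested genes, where chance gives 13.3%. The largest rise was Ccr7, the receptor that draws dendritic cells to lymph nodes, at 65.8 ± 59.7 RPKM in DKOITD (SD, n = 4) and 0 in both ITD libraries (adjusted p = 0.0372). Ccl22, a chemokine of dendritic cells, averaged 11.7 ± 4.22 RPKM (SD, n = 4) and was listed at 0 in both ITD libraries (adjusted p = 0.0334). Plxdc2 averaged 20.8 ± 7.12 RPKM (SD, n = 4) and was also listed at 0 in ITD (adjusted p = 0.0192).

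Other rises on the log2 scale were Depdc7 (4.48), Grap (3.78), Nme4 (3.76), the costimulatory ligand Tnfsf9 (3.75), Akr1e1 (3.71), Chn2 (3.71), P2ry10 (3.50), Socs2 (3.28) and Clec10a (3.04). Those of P2ry10 and Socs2 were identical against WT, so their sizes depend on the pseudocount too. The falls were Slfn4 (-3.23), Crtac1 (-2.97), Ggt1 (-2.92, listed at 0 in all DKOITD libraries), Hk3 (-2.51) and Cd63 (-2.31), a tetraspanin of granules. Flt3 at 2.88 ± 0.86 (SE; adjusted p = 0.125), Runx1 at 1.52 ± 0.52 (SE; adjusted p = 0.179), Itgam at -1.79 ± 0.46 (SE; adjusted p = 0.0863) and Ezh2 at -0.9967 ± 0.78 (SE; adjusted p = 0.585) did not pass.

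The secondary granule list was lower in DKOITD than in ITD, with 1 of 41 members down over all genes tested, or 25 down and 3 up when adjusted over the list alone (median -1.94; limma camera, adjusted p = 2.86e-14; adjusted p = 0.443 with an estimated correlation). The dendritic list was higher, with 1 of 25 members up, or 11 when adjusted over the list alone (median 1.77; adjusted p = 2.35e-08; adjusted p = 0.443 with an estimated correlation). The primary granule list was lower (adjusted p = 0.013), with 1 of 21 members down, or 7 down and 1 up when adjusted over the list alone. The B lineage list was higher (adjusted p = 0.0216), with 0 of 9 members past the threshold, or 3 when adjusted over the list alone. Its mean log2(RPKM + 1) was 0.75 and 0.84 in the ITD libraries. Genes this low can pass the filter through DKOITD libraries alone, which favours rises, and without a filter on low values the call of the B lineage list ended. The developmental regulator list was higher (adjusted p = 0.0335), with 0 of 6, or 1 when adjusted over the list alone, and here too the filter favours rises. The erythroid list was lower (adjusted p = 0.0324), with 0 of 13, or 1 up and 2 down when adjusted over the list alone. Each of these 4 lists gave an adjusted p = 0.443 with an estimated correlation. The proliferation list was lower (adjusted p = 0.0276; adjusted p = 0.684 with an estimated correlation), with 0 of 52 members past the threshold under both adjustments.

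The lists that did not pass gave adjusted p of 0.101 (NK and cytotoxic), 0.253 (early lymphoid, and eosinophil), 0.292 (immediate early), 0.496 (T lineage), 0.525 (stem and progenitor), 0.596 (monocyte), 0.692 (interferon), 0.693 (FLT3, STAT5 and MAPK) and 0.880 (PRC2 and RUNX complexes). Among these, Ccr7 of the early lymphoid list and Socs2 of the FLT3 list passed over all genes. When adjusted over the list alone, 4 NK genes rose and 1 fell, 5 early lymphoid genes rose and 3 fell, 3 genes of the FLT3 list rose and 2 fell, and 2 stem and progenitor genes rose and 1 fell. So did 1 T lineage and 1 monocyte gene (up) and 1 eosinophil gene (down), and 0 of the interferon, immediate early and complex lists. With 2 ITD libraries the gene count rested on single libraries. It was 1 without DKOITD 1, 0 without DKOITD 3, 1 without ITD 1, 0 without ITD 2, 57 without WT 2 and 156 without DKOITD 4. It was 526 with library weights and 0 with limma voom on recovered reads. The balance of rises and falls was not stable either. Without DKOITD 4, 60 rose and 96 fell, with library weights 278 rose and 248 fell, and scaled per recovered read 248 rose and 26 fell. Without ITD 1 the number of lists was 3, with the B lineage, primary granule, developmental regulator and proliferation lists losing their calls. Without ITD 2 the erythroid and developmental regulator lists lost theirs, and the erythroid mean was 3.26 in ITD 2 and 1.03 in ITD 1. The erythroid call also ended without DKOITD 4, the B lineage call without DKOITD 3, the proliferation call without DKOITD 2 or DKOITD 4, and the developmental regulator call without DKOITD 2, DKOITD 3 or WT 2. The dendritic and secondary granule lists kept their calls with each library left out. They were also the only lists to keep them under quantile normalization. Scaled per recovered read, the B lineage, developmental regulator and proliferation lists lost their calls. The direction of the proliferation test turned without ITD 1 (adjusted p = 0.995), and without DKOITD 2 the interferon list was higher (adjusted p = 0.00142).

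ITD against WT asks what the Flt3 ITD allele changes without Cre. 1 gene passed, Cd209a, at 379 ± 269 RPKM in ITD (SD, n = 2) and 0.468 ± 0.810 RPKM in WT (SD, n = 3), a log2 difference of 7.94 ± 0.77 (SE; adjusted p = 0.00248), beside 862 genes at an unadjusted p under 0.05, where chance gives 543. The groups did not overlap in 19.1% of all tested genes, where chance gives 20%. The next genes by p did not pass. They were Clec10a at 3.75, Batf3, a transcription factor of conventional dendritic cells, at 3.71, and the transferrin gene Trf at 2.96 (adjusted p = 0.0552 for each), and Cyp4v3 at 3.24 (adjusted p = 0.0706). Flt3 at 1.68 ± 0.91 (SE; adjusted p = 0.684), Ezh2 at 1.14 ± 0.83 (SE; adjusted p = 0.750), Itgam at -0.32 ± 0.48 (SE; adjusted p = 0.880) and Runx1 at -0.74 ± 0.55 (SE; adjusted p = 0.754) did not pass either.

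The dendritic cell and MHC class II list was higher in ITD, with 1 of 25 members past the threshold and 12 when adjusted over the list alone (median 1.94; limma camera, adjusted p = 8.84e-16; adjusted p = 0.851 with an estimated correlation). The interferon list was higher, with 44 of 45 members above 0 and 0 past the threshold under both adjustments (median 1.16; adjusted p = 1.51e-08; adjusted p = 0.930 with an estimated correlation). The secondary granule list did not pass (median -0.23; adjusted p = 0.106), nor did the 14 other lists tested, with adjusted p from 0.318 to 0.930. In these 0 members passed when adjusted over the list alone, except 1 of the monocyte list. Among the settings that ended the Cd209a call were the fit without ITD 2, the fit of the 2 groups alone, no filter on low values and limma voom. The gene count was 2 without DKOITD 2, 10 without WT 1, 0 without ITD 2 and 47 without WT 3, and 4 lists passed without ITD 2.

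Both DKOITD comparisons called 20 genes in common, 16 higher and 4 lower in DKOITD, and 0 in opposite directions. Among the 16 were Ccr7, Ccl22, Clec10a, Plxdc2, Socs2 and Tnfsf9, and among the 4 were Hk3, Slfn4 and Cd63. Independent lists of these sizes would share 1.26 higher and 0.316 lower genes, but the comparisons share all 4 DKOITD libraries. With the 4 DKOITD libraries divided 2 and 2 between the comparisons, the 6 divisions shared 0, 0, 4, 0, 60 and 0 genes. The 60 came with DKOITD 2 and 4 set against WT and DKOITD 1 and 3 against ITD. The count was 1 without DKOITD 1, 0 without DKOITD 3, ITD 1 or ITD 2, 48 without WT 2 and 148 without DKOITD 4.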

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

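In each of 94 measures, the DKOITD library farthest from the other 3 was compared with the group's whole range (gap divided by range, against Dixon's critical value for 4 samples), and 11 passed, where chance gives about 1 in 20, or 4.7. Both tests of the interferon pattern below were chosen after the result was seen.

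DKOITD 2 lay below the other DKOITD libraries in 8 of the measures. The interferon response list had a gap of 0.922 of the range, its members Usp18 and Phf11b 0.922 and 0.846, and the dendritic genes Cd74, H2-Aa, H2-Eb1, H2-Ab1 and Cd209a 0.950, 0.936, 0.926, 0.913 and 0.855. Shallow depth of DKOITD 2, at 2825728 reads the lowest, was tested first. Its interferon list lay -2.84 from the mean of the other 3 libraries on the log2 scale, with 45 of 45 members lowest there, while 10000 random lists matched on expression ranged from -0.60 to 0.30. Genes of like expression thus did not fall as far in general, which argues against depth alone. The random lists hold unrelated genes, whereas the estimated correlation within the interferon list was 0.72. Their range therefore does not tell how rare such a fall is. Fewer dendritic-type cells in that library would lower the dendritic list by at least as much, but that list lay -1.61 away, and the interferon list fell further, by a difference of -1.23 ± 0.24 (SE over genes). That SE treats the genes as independent, so it cannot decide whether fewer such cells were the source. No biological explanation was tested, since the labels name nothing that sets DKOITD 2 apart, and the genes of a list are not independent.

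Cdkn1a was highest in DKOITD 3 (0.873 of the range). Crtac1 was above 0 in DKOITD 4 and Beta-s in DKOITD 3, each with the other 3 libraries at 0 (a gap of 1 times the range).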

How the results depend on the processing

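The alternatives chosen after seeing the data were scaling per recovered read, voom, the label number series and the 2 pairs left out. For DKOITD against WT, 1380 genes became 733 without a filter, 884 with the replicate block, 2772 per recovered read, 4 with the number series as a term, 792 without WT 2 and DKOITD 2 and 735 without WT 2 and DKOITD 4, and ranged from 541 to 1962 with each library left out. For DKOITD against ITD, 23 became 4 with the stricter filter, 42 with quantile normalization, 526 with library weights, 46 with the 2 groups alone, 57 with the replicate block, 274 per recovered read, and 0 with voom and with the number series (0 to 156 with each library left out). For ITD against WT, 1 became 2 with a pseudocount of 0.1, 3 without a filter, and 0 with the 2 groups alone, the replicate block and voom (0 to 47). Lists past the threshold numbered 4 with quantile normalization for DKOITD against WT (7 in the fit of the results; 4 to 8 with each library left out; 5 to 8 under the other alternatives), and 0 with an estimated correlation in all 3 comparisons. For DKOITD against ITD they numbered 4 without a filter, 2 with quantile normalization and 4 per recovered read (7 in the fit of the results; 3 to 8 with each library left out; 5 to 9 under the other alternatives), and for ITD against WT 2 to 4 with each library left out. Genes shared by both DKOITD comparisons (20) numbered 4 with the stricter filter, 40 with quantile normalization, 371 with library weights, 56 with the replicate block, 248 per recovered read, 0 with voom, 0 with the number series, 66 without WT 2 and DKOITD 2, 194 without WT 2 and DKOITD 4, and 0 to 148 with each library left out.

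The test of 2 lists turned direction in DKOITD against ITD: interferon response without DKOITD 2 (adjusted p = 0.00142; 0.00142 to 0.654 with each library left out) and proliferation without ITD 1 (adjusted p = 0.995; 2.31e-05 to 0.995). Leaving out 1 ITD library leaves 1, assumed to vary like the other groups. Of 56 named genes called in DKOITD against WT, 38 kept their call with each library left out and 2 under every alternative. The series term left DKOITD 4 as the sole DKOITD library beside WT, so that fit also compares fewer libraries. The cause of the other changes was not tested. No called gene turned direction, and 76 signs turned among results past the threshold in neither fit. Scaling per recovered read moved the median log2 difference of all genes between DKOITD and WT from 0.17 to 0.74, and quantile normalization to -0.03. The replicate block gave 6, 9 and 3 lists in the 3 comparisons, without the primary granule and proliferation lists for DKOITD against WT, the erythroid list for DKOITD against ITD and Cd209a for ITD against WT. Replicate numbers do not pair the libraries: deviations of same-numbered DKOITD and WT libraries correlated at -0.02, 0.07 and 0.06. Depth between 2825728 and 23124435 reads, from 100 cells each, limits what can be said of low genes.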

Other observations

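The erythroid genes, beyond the list test, were held by 3 of the 9 libraries. The list's mean log2(RPKM + 1) was 3.21 in WT 1, 2.89 in WT 2 and 3.26 in ITD 2, and between 0.970 and 1.41 in the 6 others. Alas2, the first enzyme of haem synthesis in red cells, measured 49.6, 37.8 and 27.1 RPKM in those 3 libraries and at most 1.28 RPKM elsewhere. The carbonic anhydrase Car2 measured 54.0, 42.5 and 118 RPKM there and at most 8.10 RPKM elsewhere. These genes and the next were chosen after their values were seen.

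The labels give no sex. Xist, transcribed from the inactive X chromosome, was above 7 RPKM in DKOITD 3 (8.41), DKOITD 4 (7.95), ITD 2 (8.20), WT 2 (21.4) and WT 3 (11.03). The Y-linked gene Ddx3y was listed at 0 in those 5 and measured 13.4, 21.5, 13.2 and 21.4 RPKM in DKOITD 1, DKOITD 2, ITD 1 and WT 1.

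The tests of the patterns below were chosen after the results were seen, apart from the other splits of the libraries, which were planned. When the 7 DKOITD and WT libraries were divided 4 and 3 in all 35 ways, only the genotype split itself gave 1380 changed genes, and the highest other gave 150. That argues against chance for the count, but 1 of 35 is the smallest share this design allows, so chance is not excluded. The split that follows the label number series gave 130 genes. For lists, 2 of the 35 splits gave as many as the genotypes (7; highest other 7), so chance is not excluded for the number of lists. The other split with 7 lists put DKOITD 1, DKOITD 2, WT 1 and WT 2 together and gave 0 changed genes. The lowest number of lists in any split was 1. The list test at the preset correlation thus also passed lists where genotypes were mixed, so its small p-values alone do not tie a list to genotype.

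Dendritic and class II genes were higher in DKOITD than in WT, and fewer neutrophils with all other cells alike would raise every other type's genes alike, but the dendritic list mean less that of 6 other cell-type lists differed by 3.93 on the log2 scale (exact permutation test, two-sided, p = 0.0286, the smallest possible; n = 4 and 3). The dendritic list was picked after its rise was seen, so that p does not weigh chance. In WT the T and B lineage means lay between 0.66 and 1.28, where the pseudocount damps a rise. The erythroid mean was high in WT 1 and WT 2 (3.21 and 2.89), which widens the contrast. The monocyte list, well above that floor, overlapped between the groups (4.92 to 5.38 in DKOITD, 4.29 to 5.18 in WT). The NK list stood higher in DKOITD (3.46 to 4.57 against 2.11 to 2.99). Under 3 other scalings the dendritic list stayed at least 3.28 above the median of all genes. Median-of-ratios and per-read scaling multiply a library by a constant, which moves list and median nearly alike, so they could hardly change that gap. Only quantile normalization, where the list stood 3.38 above, bears on scaling. For B cells in the gate the genes went both ways. Cd79a, Ms4a1, Pax5 and Ebf1, chosen after the results were seen, reached at most 0.603 RPKM in DKOITD. The 9 tested B lineage genes were on average low in WT, where the filter favours rises. Of these, however, 7 stood higher in DKOITD than in WT and 2 lower, with Fcrla, Cd79b and Spib past the threshold. B cells are therefore not excluded. With the label number series as a term the list mean differed by 4.46 ± 1.01 and the series term was -0.36 ± 1.01 (SE, linear model over 9 libraries), which speaks for the genotype, but DKOITD 4 alone carries the difference, so series and genotype cannot be told apart. A hypothesis is that the genotype may raise either the share of dendritic-type cells in the gate or their transcript per cell, which cannot be told apart in sums of 100 cells.

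Secondary granule genes were lower in DKOITD than in WT. Under 3 other scalings the list stayed at -1.89 or further below the median of all genes. Median-of-ratios and per-read scaling move list and median nearly alike, so only quantile normalization, which gave the -1.89, bears on scaling. Fewer neutrophil-lineage cells of every stage would lower the primary granule list as much, and the primary less secondary list mean differed by 1.40 on the log2 scale with overlapping groups (exact permutation test, two-sided, p = 0.143; n = 4 and 3). With the label number series as a term the secondary list mean differed by -1.07 ± 0.771 and the series term was -1.14 ± 0.771 (SE, linear model over 9 libraries), which leans to neither, so series and genotype cannot be told apart with 1 DKOITD library in the WT series. A loss of all stages and a loss of mature cells alone cannot be told apart with libraries that overlap this far.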
